A study of Mus musculus with 6 samples.

How the data were processed

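Hypothalamus from C57BL/6J mice aged 8 weeks was profiled by Drop-seq, a droplet method that tags the 3' end of each captured transcript with a cell barcode and a unique molecular identifier (UMI). There were 6 libraries, 3 from wild-type animals (WT1, WT2 and WT3) and 3 from animals lacking IDOL (KO1, KO2 and KO3). Per the labels, the groups were mixed over 2 days of library preparation, but the day of each library was not given, so day could not enter any test. The labels did not say whether each library came from its own animal, nor which part of Mylip, the gene of IDOL, was deleted. The p-values therefore measure the spread between libraries. The authors deposited one table of raw UMI counts per gene and cell barcode, and the submitters' notes named bcl2fastq, STAR 2.5.0c and the genome builds mm10 and GRCm38. The counting program, the gene annotation, the strand counted and the rule that picked cell barcodes were not stated. The table held 18204 genes, each with a UMI in at least 3 cells, and 13994 barcodes, each with at least 200 genes. Of the gene symbols, 93.9% matched GENCODE M21, which supplied the coordinates on GRCm38. The symbols were the only gene identifiers in the table.

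Cells were kept with at least 300 detected genes and at most 20% mitochondrial UMIs. Of the barcodes, 3965 had fewer genes and 1247 had more mitochondrial UMIs, and 9449 passed. Scrublet in scanpy 1.11.5, run per library with an expected doublet rate of 5%, called 120 doublets (1.27% of passing cells), which were removed. The 9329 cells left were clustered without genotype. Counts were scaled per cell and log-transformed, 2000 variable genes and 30 principal components were used (scikit-learn 1.9.0), and Leiden clustering at resolution 1 ran on a graph of 15 neighbours (igraph 0.11.9, leidenalg 0.10.2). This gave 24 clusters. The 11 clusters of at least 60 cells that carried markers of more than 1 class were split again, with 1000 variable genes, 10 components and resolution 0.5.

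Clusters were named from fixed marker lists for neurons, astrocytes, oligodendrocytes, newly formed oligodendrocytes, oligodendrocyte precursors (OPC), microglia, perivascular macrophages, endothelial cells, mural cells, fibroblasts, tanycytes, ependymal cells, pituitary, choroid plexus, red blood cells and lymphocytes or neutrophils. A name needed 3 markers at 4-fold over the median cluster and a mean scaled marker score of 0.5. Among the 10 leading genes, markers of another class could not outnumber the class's own. Clusters that met no name stayed unnamed. Neurons were clustered again at the same resolution. A cluster was called GABAergic where the sum of Gad1, Gad2 and Slc32a1 was at least 4 times Slc17a6, and glutamatergic where Slc17a6 was at least that sum, each with 3 markers at 50 CPM. The marker lists were fixed before the data were examined, but the scoring rule was set after the cells had been seen. Every class name is thus marker-defined and stands for cells like that type.

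UMI counts were summed per library over all cells and over each class with at least 20 cells in every library, because cells of a library are not replicates. The sums were tested with edgeR 4.0.16 under R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F-test, default settings). P-values were adjusted by Benjamini-Hochberg within a class at 0.05, and a count adjusted over all classes together stands beside it. Mylip was tested whatever the filter said. Quasi-likelihood fits with robust settings were looked at first. The default settings were taken because the plan named no robust option, and the robust fit is given as an added alternative. Unless stated otherwise, expression is in counts-per-million (CPM) of the UMIs of the tested genes of a class, TMM-scaled. Mylip, mt-Nd3 and a few other genes are given as CPM of all UMIs of the class, in which case the text says so. Log2 fold changes are KO over WT ± SE (absolute log2 fold change over the square root of F), and group levels are mean ± SD of 3 libraries. Where a group had 0 UMIs of a gene, the fold was computed against a floor of 3 UMIs over the whole group. With 1 to 3 UMIs it was given as a ratio with an exact 95% interval. Intervals and floors cover counting error only.

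Neurons were set against all other cells by an edgeR interaction test with library as a block. Class shares and per-cell depth were compared by two-sided exact permutation tests, for which 3 against 3 libraries allow no p below 0.1. Counts of genes whose groups did not overlap stand beside the 10% that chance gives.

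Before the data were examined, 20 gene lists were fixed. These covered IDOL targets and lipoprotein uptake, cholesterol synthesis, LXR targets, orexigenic peptides and receptors, anorexigenic peptides and receptors, other hypothalamic peptides, GABA and glutamate transmission, synaptic vesicle release, insulin and leptin signalling, nuclear-encoded respiratory chain, the mitochondrial genome, glycolysis, cytosolic ribosomal proteins, immediate early genes, heat shock, inflammation, interferon response, genes near Mylip on chromosome 13, Y-linked genes with Xist, and tissue next to the hypothalamus. A list with at least 5 tested members in a class was tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over all lists and classes. Camera with an estimated correlation and fry ran beside it, and the fry results are not reported here.

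The genes named in the text followed a rule that was also set before the data were examined. Mylip, Vldlr, Lrp8 and Apoe were always named where tested. Some genes that the rule picked are not reported here. In all cells and neurons up to 10 higher and 10 lower genes were named that passed and whose groups did not overlap, or the next by p up to 5 per direction. Other classes had up to 4 per direction, or 2 where none passed. Called lists gave 3 members each and the interaction test 5 genes. Mitochondrial, ribosomal and Y-linked genes and Xist were named with their lists.

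The alternatives planned before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no gene filter, at least 500 genes per cell, doublets kept, the replicate number as a block, Leiden resolution 0.5, camera with an estimated correlation, and leaving out each library in turn. Robust fits, fits without certain clusters, lists without mt-Nd3 or Mylip, and genes per cell after thinning each cell to 500 UMIs were added after the data had been seen.

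The tests were run on simulated counts drawn from the means, spreads and library sizes of these libraries, with genes changed by 1.5, 2 or 4-fold. In all cells edgeR recovered 0, 14.7 and 72.5% of these and made 68 calls of which 8 were false, while DESeq2 recovered 1.59, 36.8 and 73.9% with 95 calls of which 18 were false. In neurons edgeR recovered 21.4, 64.0 and 97.1%, in oligodendrocytes 10.5, 44.4 and 88.7%, and in microglia 14.5, 36.5 and 90.1%. For the interaction, 77.0% of genes changed 4-fold in neurons were recovered, with 170 calls of which 16 were false. Far more genes were changed in the simulation than passed in the real data. In microglia 55, 74 and 71 of 659 genes were changed, while 2 of 738 passed in the real data. For the interaction 200 of 12198 were changed, while 1 of 12410 passed. More changed genes loosen the Benjamini-Hochberg cutoff, so these percentages may overstate recovery where few genes change. Mylip itself did not pass over all cells in edgeR. A list shifted by 1.3-fold in all cells was called, and none of the other lists was. Genes were drawn independently there, so false list calls from correlation between genes were not tested. No library pair held one library in duplicate, since the counts of every pair differed by a chi-square per degree of freedom of 4.22 to 19.6.

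Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps. Mural and ependymal cells were left out of the gene tests because a library held under 20 of them. No separate correction for free RNA was made, and no sequence reads were available, so read positions could not be examined.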

Results

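The comparison asked how loss of IDOL, the ubiquitin ligase encoded by Mylip that marks the lipoprotein receptors VLDLR and ApoER2 for breakdown, altered gene expression in the cell types of the mouse hypothalamus. Drop-seq libraries from 3 wild-type and 3 IDOL knockout preparations gave 2744, 1410 and 1717 cell barcodes in WT1, WT2 and WT3 and 2331, 2929 and 2863 in KO1, KO2 and KO3. Their total UMI counts were 4068886, 1670993 and 2096119 in the WT libraries and 3057822, 3213664 and 3053421 in the KO libraries. After filtering, 1874, 1028 and 1148 WT cells and 1466, 1869 and 1944 KO cells remained, with 1500298 to 3647575 UMIs per library. Median UMIs per cell were 918 ± 88.3 (SD, n = 3 libraries) in WT and 860 ± 95.2 in KO (two-sided exact permutation p = 0.5), and median genes per cell were 628 ± 57.0 and 585 ± 44.4 (exact permutation p = 0.4). With cells thinned to 500 UMIs the median was 381 ± 10.4 genes in WT and 385 ± 3.00 in KO (exact permutation p = 0.9).

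Neurons were the most numerous class, with 34.2 ± 8.74% of cells in WT and 31.7 ± 7.21% in KO (mean ± SD, n = 3 libraries per group). They held a cluster with Vip, Nms and Vipr2, peptide and receptor genes typical of the suprachiasmatic nucleus, and clusters with Pomc, with Npy and Agrp, with Oxt and Avp, with Ghrh and Th, and with Hdc. GABAergic cells made up 22.1 ± 5.21% of cells in WT and 21.5 ± 7.38% in KO, and glutamatergic cells 5.18 ± 2.36% and 3.76 ± 0.709%. Astrocytes followed with 17.7 ± 3.14% and 17.2 ± 1.99%, oligodendrocytes with 14.4 ± 3.82% and 13.8 ± 1.88%, and endothelial cells with 7.95 ± 2.17% and 9.07 ± 3.34%. OPC held 5.58 ± 0.806% of cells in WT and 6.98 ± 0.417% in KO, and perivascular macrophages 0.460 ± 0.173% and 0.784 ± 0.261%. In these 2 of 17 classes the groups did not overlap, where chance gives 10% of classes. Both had an exact permutation p of 0.1, the smallest this design allows, and an adjusted permutation p of 0.85. Microglia held 4.63 ± 1.55% and 3.94 ± 0.426%, and tanycytes, the glia lining the third ventricle, 5.71 ± 2.03% and 3.48 ± 1.63% (exact permutation p = 0.3). The unnamed share was 2.66 ± 1.40% in WT and 4.50 ± 1.85% in KO (exact permutation p = 0.3), and fibroblast-like cells held 0.562 ± 0.442% and 1.84 ± 1.72%, with 72 of them in KO3. The count of classes whose groups did not overlap was 1 with at least 500 genes per cell, 4 without WT3 and 5 without KO2, where chance gives 20% of classes with 1 library left out.

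**Figure D1:**
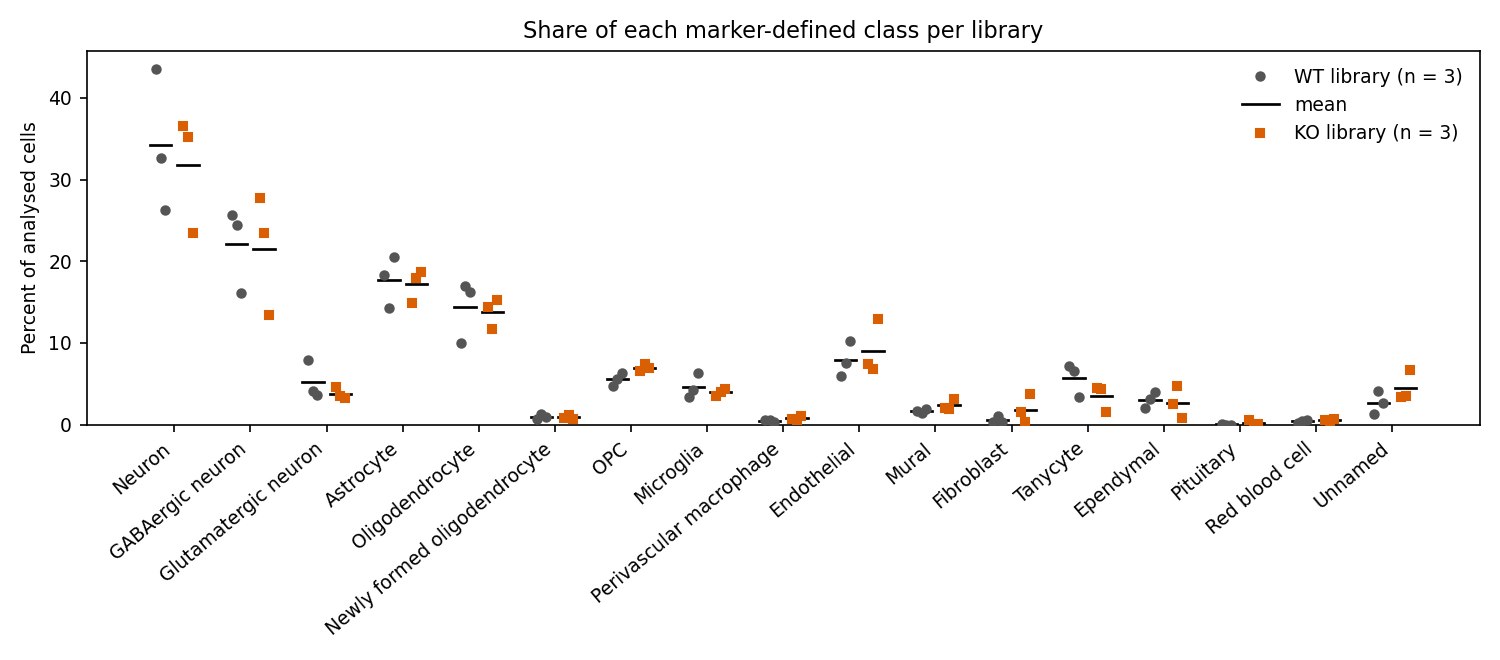
Percent of analysed cells per class on the vertical axis, one point per library (WT and KO), with lines at the group means. Groups overlapped in 15 of 17 classes, and OPC and perivascular macrophages were higher in all 3 KO libraries.

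Mylip (chromosome 13, 45389742 to 45412022 on GRCm38, plus strand) was at or near 0 UMIs in the KO libraries. Over all cells the WT libraries held 68, 27 and 43 Mylip UMIs and the KO libraries 2, 0 and 0, or 20.0 ± 2.98 and 0.272 ± 0.471 CPM of all UMIs (mean ± SD, n = 3 libraries per group). The WT to KO ratio was 78.3, with a 95% counting interval of 21.3 to 653. The same pattern held in neurons, with 30, 6 and 5 UMIs against 1, 0 and 0, a ratio of 40.9 (6.94 to 1654). It held in microglia too, where WT libraries had 7, 11 and 12 Mylip UMIs (241 ± 99.0 CPM of all microglial UMIs) and KO libraries none, which is at least 11-fold lower in KO. In astrocytes 12, 5 and 5 UMIs stood against 0 (at least 8.39-fold lower), in GABAergic neurons 12, 5 and 2 against 0 (at least 7.05-fold) and in endothelial cells 6, 1 and 9 against 0 (at least 7.0-fold). Mylip fell in neurons (log2 fold change -4.84 ± 0.78, edgeR adjusted p = 0.00982) and in microglia (-6.43 ± 1.19, edgeR adjusted p = 0.0183). Over all cells edgeR gave -6.04 ± 0.65 with an adjusted p of 0.0808, which did not pass among 13057 genes. The DESeq2 Wald test gave 7.6e-05, the fit with no gene filter 0.0193, and the adjusted p ranged from 7.6e-05 to 0.489 over its alternatives. In neurons the call was lost with DESeq2 (adjusted p = 0.385), without WT1 (edgeR 0.478) and without KO2 (0.115), within a range of 2.2e-05 to 0.478, and the log2 fold change was -6.68 without KO1. In microglia it was lost with robust settings (0.0859) and without WT2 (0.405), WT3 (0.349), KO1 (0.0773), KO2 (0.172) or KO3 (0.130), within a range of 3.7e-06 to 0.405 (edgeR adjusted p).

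**Figure D2:**
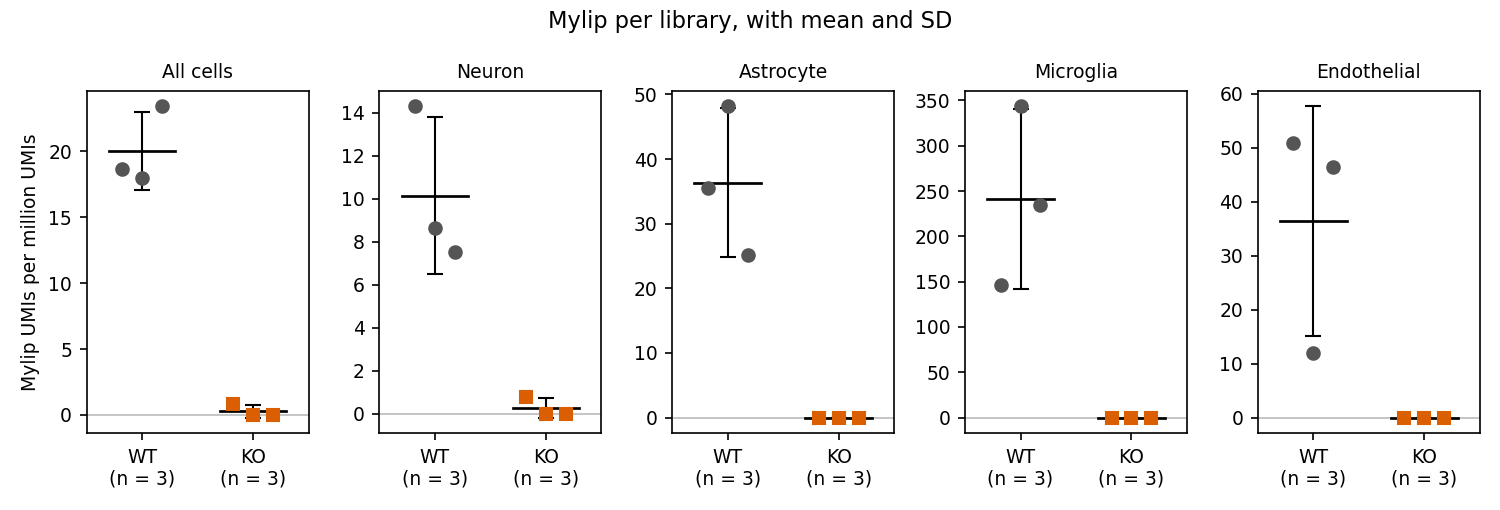
Mylip CPM of all UMIs on the vertical axis, per library in WT and KO, in all cells, neurons, astrocytes, microglia and endothelial cells, with mean ± SD of 3 libraries per group. All KO points were at or near 0, and the WT mean over all cells was 20.0.

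Vldlr, Lrp8 and Apoe, 2 receptors that IDOL acts on and their ligand, showed no difference that passed in any class tested. These are transcript levels, and the receptor proteins that IDOL marks for breakdown were not measured. Over all cells Vldlr stood at 84.6 ± 6.02 CPM in WT and 99.5 ± 3.99 in KO (log2 fold change 0.23 ± 0.15, n = 3 per group). Lrp8, which encodes ApoER2, gave 0.13 ± 0.19, and Apoe, which turned to 0.054 without KO1, gave -0.12 ± 0.23. In neurons the values were 0.31 ± 0.18 for Vldlr, 0.15 ± 0.21 for Lrp8 and -0.26 ± 0.22 for Apoe. Vldlr gave 0.68 ± 0.26 in glutamatergic neurons (115 ± 24.6 against 189 ± 20.1 CPM, edgeR adjusted p = 0.692), 0.27 ± 0.21 in GABAergic neurons, 0.22 ± 0.21 in oligodendrocytes and 0.03 ± 0.35 in OPC. Apoe in microglia gave -1.67 ± 0.38 with an edgeR adjusted p of 0.0806. It passed without WT1 (0.0392), without WT3 (0.0289), with the replicate block and with no gene filter, within a range of 1.8e-09 to 0.998. Apoe in the other classes lay between -0.34 ± 0.22 in GABAergic neurons and 0.18 ± 0.20 in oligodendrocytes. Lrp8 gave 0.15 ± 0.23 in GABAergic neurons, 0.24 ± 0.45 in astrocytes and 0.34 ± 0.54 in tanycytes.

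Over all cells, the genes that came nearest to passing besides Mylip were Gm8773, Gpr137b-ps and mt-Nd3. Gm8773 (chromosome 5, 5573799 to 5576203) was lower in KO, with a log2 fold change of -2.78 ± 0.38 (edgeR adjusted p = 0.275). Gpr137b-ps (chromosome 13, 12615057 to 12650388), a transcribed pseudogene of the lysosomal membrane protein gene Gpr137b, had 0 UMIs in WT and 13, 18 and 22 in KO, at least 15.6-fold higher (adjusted p = 0.347 in edgeR). The mitochondrial gene mt-Nd3, a subunit of respiratory complex I, had 0 UMIs in the WT libraries and 285, 732 and 104 in the KO libraries, at least 329-fold higher (edgeR adjusted p = 0.347). None of 13057 genes passed in edgeR. At an unadjusted p under 0.05 there were 262 (2.01%, 167 higher and 95 lower), less than the share of 0.05 that chance gives. In single classes this percentage ran from 3.16% in tanycytes to 6.82% in OPC. Over all cells 971 genes (7.44%) had groups that did not overlap, where chance gives 10%. The DESeq2 Wald test called 4, Gm8773, Gpr137b-ps, mt-Nd3 and Mylip. Next by p among the higher genes were Slc15a2 (0.90 ± 0.20), Clmp (0.93 ± 0.22), Ccl5 (2.66 ± 0.65) and Grcc10 (1.5 ± 0.38). Among the lower genes they were Gabra2, a GABA receptor subunit (-0.90 ± 0.21), Ly86 (-1.87 ± 0.45) and Tac1 (-1.20 ± 0.32), all at an edgeR adjusted p of 1.00. In edgeR 1 gene passed without KO2 (Rbp4), 1 without KO3 (mt-Nd3), 1 with the replicate block (mt-Nd3) and 1 with no gene filter (Mylip).

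In KO neurons Tac1 and Gm8773 fell with Mylip, and mt-Nd3 was counted in KO neurons only. Tac1 (chromosome 6, 7554879 to 7565834), which encodes the neuropeptide substance P, went from 446 ± 91.9 CPM in WT to 176 ± 75.8 in KO (log2 fold change -1.33 ± 0.23, n = 3 per group, edgeR adjusted p = 0.0147). Gm8773 went from 32.6 ± 9.44 to 4.99 ± 2.99 CPM (-2.65 ± 0.41, edgeR adjusted p = 0.00777). mt-Nd3 was at least 204-fold higher in KO neurons, where WT neurons had 0 UMIs (edgeR adjusted p = 3.8e-05). These were 4 of 9809 genes tested, 1 higher and 3 lower, and the same number passed when adjusted over all classes. At an unadjusted p under 0.05 there were 434 (220 higher, 214 lower), and 977 (9.96%) had groups that did not overlap, against 10% by chance. Genes next by p did not pass. They included Gnrh1, the gonadotropin-releasing hormone gene (2.84 ± 0.57), Nts, neurotensin (1.62 ± 0.33), Grcc10 (1.54 ± 0.32) and Marcks (0.64 ± 0.17) on the higher side, and Nr4a2 (-1.37 ± 0.31) and Gabra2 (-0.77 ± 0.19) on the lower, with edgeR adjusted p from 0.10 for Gnrh1 to 0.774 for Marcks. Gnrh1 ran from 1.97 without KO3 to 8.24 without WT1 and passed without WT1 (edgeR adjusted p = 3.0e-05), without KO1 (0.0288), with the replicate block and with no gene filter, over a range of 3.6e-41 to 0.999. Its UMIs came mostly from 1 cell each in WT1 (159 of 162), KO1 (168 of 168), KO2 (199 of 202) and KO3 (442 of 477). Nts passed without KO1 (edgeR adjusted p = 0.0288), without KO2 (0.0430), with the replicate block and with no gene filter. Grcc10 passed without KO3 (0.0149), with the replicate block and with no gene filter. Gabra2 passed without KO3 (0.0369) and with no gene filter, and Nr4a2 with no gene filter only. The Tac1 call was lost with DESeq2 (adjusted p = 0.822), with robust settings (edgeR 0.982), without WT3 (0.0982) and without KO2 (0.110), over a range of 6.5e-11 to 0.982. Gm8773 was lost without KO2 (0.0577, range 5.1e-08 to 0.0577) and mt-Nd3 with robust settings (0.989, range 1.3e-86 to 0.989), and the count of passing genes was 8 without KO1, 2 without KO2 and 8 without KO3 (edgeR adjusted p).

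Gm8773 fell and Nts rose in GABAergic neurons. Nts (chromosome 10, 102481756 to 102490486), a peptide that curbs feeding, went from 32.5 ± 28.4 CPM in WT to 236 ± 199 in KO (log2 fold change 2.54 ± 0.47, n = 3 per group, edgeR adjusted p = 0.0479). Gm8773 went from 47.9 ± 11.9 to 6.87 ± 4.14 CPM (-2.81 ± 0.39, edgeR adjusted p = 0.00120), and mt-Nd3 was at least 113-fold higher in KO (edgeR adjusted p = 2.5e-05). In glutamatergic neurons Nnat (chromosome 2, 157560078 to 157562522), an imprinted gene for neuronatin, fell from 765 ± 185 to 341 ± 85.1 CPM (-1.13 ± 0.21, edgeR adjusted p = 0.0299). In GABAergic neurons 3 of 8861 genes passed and 391 had an unadjusted p under 0.05, and 906 (10.2%) had groups that did not overlap, against 10% by chance. In glutamatergic neurons these were 1 of 4155, 262 and 503 (12.1%). The Nts call was lost with DESeq2 (adjusted p = 1.00), with at least 500 genes per cell (edgeR 0.104), doublets kept (0.138), the replicate block (0.60), Leiden resolution 0.5 (0.117), robust settings (0.985), and without WT2 (0.808), WT3 (0.584) or KO3 (0.185), over a range of 4.5e-25 to 1.00. Its log2 fold change ran from 1.61 without KO3 to 3.82 without WT1, and 168 of the 324 Nts UMIs of KO3 over all cells came from 1 cell. The Nnat call was lost with the replicate block (edgeR adjusted p = 0.0805), Leiden resolution 0.5 (0.0803) and without WT2 (0.473), KO2 (0.539) or KO3 (0.116), over a range of 2.1e-04 to 0.539, and mt-Nd3 in GABAergic neurons with robust settings (0.985).

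Ly86 fell in microglia, the immune cells of the brain. This gene (chromosome 13, 37345208 to 37419036), whose product MD-1 pairs with a Toll-like receptor relative, went from 2819 ± 305 CPM in WT to 725 ± 176 in KO (log2 fold change -1.92 ± 0.25, n = 3 per group, edgeR adjusted p = 2.5e-04). Scrg1 (chromosome 8, 57455923 to 57477585) fell in oligodendrocytes from 486 ± 146 to 103 ± 29.7 CPM (-2.28 ± 0.26, edgeR adjusted p = 4.3e-05). In astrocytes Hbb-bs (chromosome 7, 103826534 to 103828096), a haemoglobin chain of red blood cells, rose from 42.9 ± 1.70 to 159 ± 52.4 CPM (1.81 ± 0.36, edgeR adjusted p = 0.0191). Cells named red blood cells numbered 3, 5 and 6 in WT and 8, 6 and 14 in KO. mt-Nd3 was at least 35.8-fold higher in KO astrocytes (edgeR adjusted p = 4.7e-06) and at least 38.7-fold higher in KO oligodendrocytes (edgeR adjusted p = 0.00154), the latter named after its value was seen. Ly86 and Mylip were the 2 of 738 genes that passed in microglia (44 at an unadjusted p under 0.05), and 1 of them, Ly86, passed when adjusted over all classes. In astrocytes 2 of 4197 passed (186 at p under 0.05) and in oligodendrocytes 2 of 4230 (273). Groups did not overlap for 88 microglial genes (11.9%), 371 astrocyte genes (8.84%) and 503 oligodendrocyte genes (11.9%), against 10% by chance. The Hbb-bs call was lost with DESeq2 (adjusted p = 0.162), without WT1 (edgeR 0.215), WT3 (0.120), KO1 (0.0959) or KO2 (0.185), over a range of 7.7e-04 to 0.215, and mt-Nd3 in astrocytes with DESeq2 (0.0590) and robust settings (1.00). In oligodendrocytes mt-Nd3 was not called with robust settings or with at least 500 genes per cell. The number of passing genes was 1 without WT3 and 0 without KO2 in astrocytes, 5 without KO1 in oligodendrocytes, and 7 without WT1, 1 without WT2, 5 without KO1 and 1 without KO2 in microglia.

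**Figure D3:**
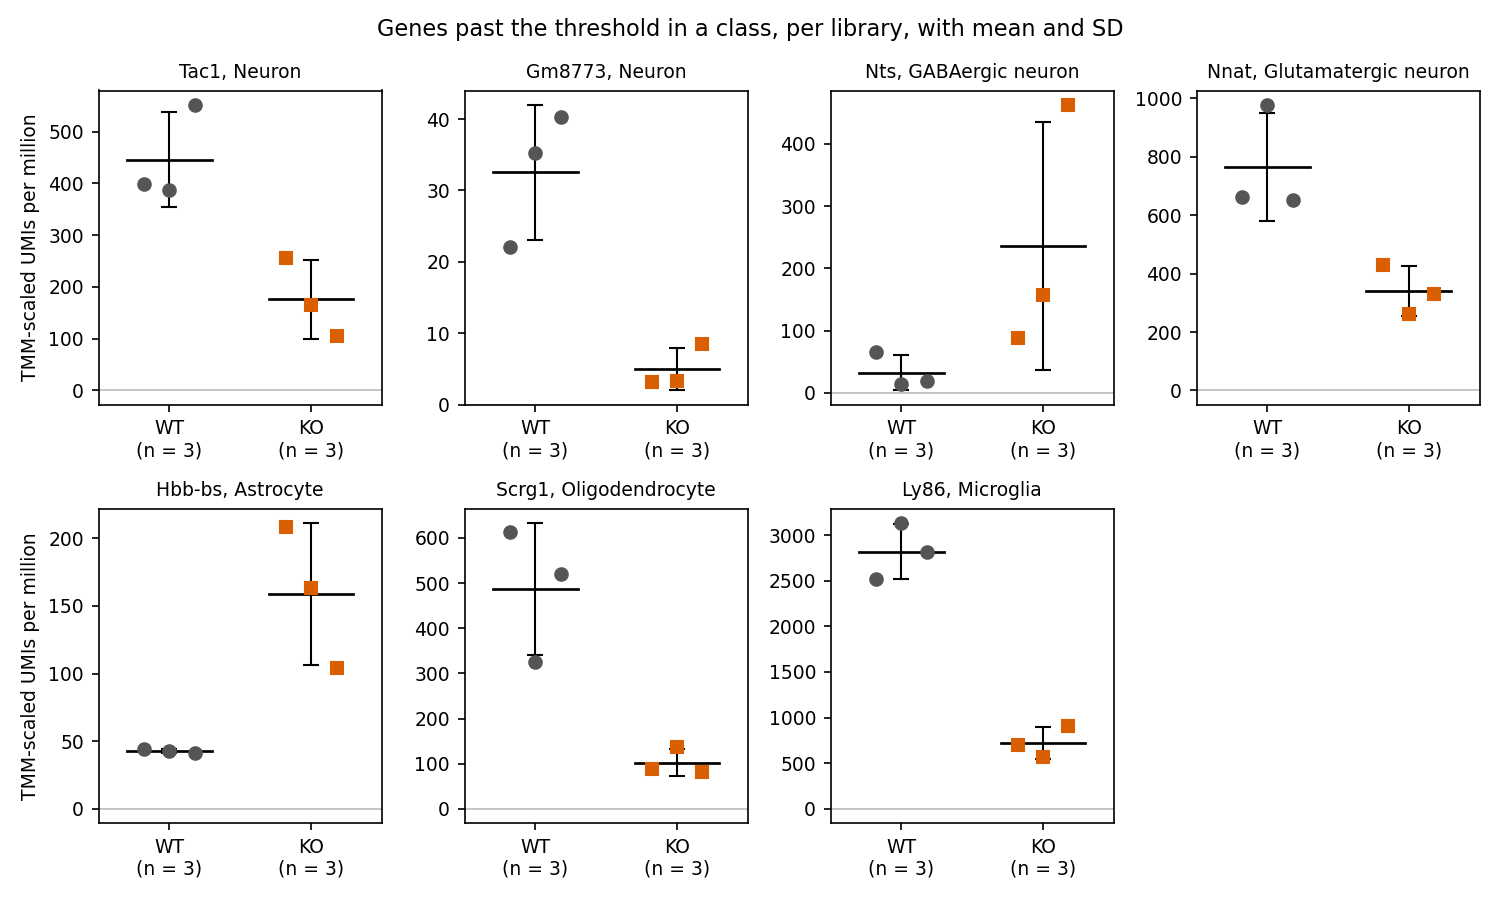
TMM-scaled CPM on the vertical axis, per library in WT and KO, with mean ± SD of 3 libraries, for Tac1 and Gm8773 in neurons, Nts in GABAergic neurons, Nnat in glutamatergic neurons, Hbb-bs in astrocytes, Scrg1 in oligodendrocytes and Ly86 in microglia. The KO and WT points of each gene did not overlap, which the rule for naming genes required. The means of Ly86 were 2819 in WT and 725 in KO.

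OPC, endothelial cells and tanycytes held no gene that passed. In OPC the genes nearest to passing were Kmt2a, a histone methyltransferase (log2 fold change 1.08 ± 0.32, and 1.70 without WT3), Sox4 (1.01 ± 0.31), Impa1 (-1.61 ± 0.53) and Wdr1 (-0.97 ± 0.32), with an edgeR adjusted p of 0.613 for each. In endothelial cells they included Kdr, a receptor for vascular endothelial growth factor (0.90 ± 0.26), Cers4 (1.10 ± 0.39) and Zbtb16 (-1.66 ± 0.40), each at an edgeR adjusted p of 0.998. In tanycytes they were Bex4 (1.28 ± 0.36), Ttc28 (1.10 ± 0.35), Mtus1 (-2.23 ± 0.51) and Cct5 (-1.12 ± 0.32), at an edgeR adjusted p of 0.968 to 0.999. edgeR tested 2127, 2449 and 3102 genes and passed 0 in each class, with 145, 101 and 98 at an unadjusted p under 0.05, and the DESeq2 Wald test also passed 0. Groups did not overlap for 244 (11.5%), 213 (8.70%) and 250 (8.06%) genes, against 10% by chance. In OPC edgeR passed 2 genes without WT2 and 1 without WT3, KO1, KO2 or KO3. In endothelial cells it passed 2 without WT3 and 1 without KO3, and in tanycytes 2 without KO3.

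Nuclear genes of the respiratory chain were shifted down as a list in KO neurons, with 55 of 68 members lower and 13 higher (camera adjusted p = 0.00797, and adjusted p = 0.913 with an estimated correlation). List calls were as frequent under other groupings of the libraries. Of the 10 splits of the 6 libraries into 3 and 3, 8 called at least the 21 lists of the real split. The highest other called 48, so the number of list calls here and in the next paragraphs does not set KO apart. The respiratory chain members with the smallest p were Ndufa8 of complex I (log2 fold change -0.37 ± 0.15), Cycs, cytochrome c (-0.41 ± 0.19), and Cox5b (-0.32 ± 0.16), and none passed, adjusted over the list alone or over all genes. The list was also called down over all cells (55 of 68 lower, adjusted p = 0.0119), in GABAergic neurons (49 of 68, 0.0409) and in glutamatergic neurons (54 of 66, 0.00110), each with an adjusted p = 0.913 with an estimated correlation. In glutamatergic neurons its members with the smallest p were Cox5a (-0.47 ± 0.18), Ndufa12 (-0.56 ± 0.22) and Atp5b (-0.38 ± 0.17). The call over all cells was lost without WT1 (0.458), WT3 (0.283), KO1 (0.0627) or KO2 (0.229), and in neurons without WT3 (0.711), KO1 (0.0860) or KO2 (0.133). In GABAergic neurons it was lost with the replicate block (0.0501) and without WT1 (0.310), WT3 (0.918), KO1 (0.372) or KO2 (0.223), and in glutamatergic neurons with at least 500 genes per cell (0.0643), without WT3 (0.0847) or KO1 (0.102), the adjusted camera p ranging from 2.5e-06 to 0.918 over the alternatives.

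Cytosolic ribosomal protein genes were shifted up as a list, with 47 of 61 members higher over all cells (camera adjusted p = 1.0e-04, and adjusted p = 0.913 with an estimated correlation). Rps16 (log2 fold change 1.10 ± 0.26), Rps21 (0.59 ± 0.19) and Rps12 (0.63 ± 0.22) had the smallest p. The list was also called up in neurons (42 of 61 higher, adjusted p = 1.2e-04), GABAergic neurons (42 of 61, 0.00941), glutamatergic neurons (39 of 58, 0.0193), endothelial cells (34 of 58, 0.0193) and tanycytes (37 of 54, 0.0124), each with an adjusted p = 0.913 with an estimated correlation. No member passed over all genes, and adjusted over the list alone 1 was higher in neurons (Rps16, 1.09 ± 0.24) and 1 in glutamatergic neurons (Rps21, 0.70 ± 0.18). Rps16 gave 1.00 ± 0.27 in GABAergic neurons and 1.68 ± 0.47 in endothelial cells, and Rpl10 gave -1.0 ± 0.32 in glutamatergic neurons (from -0.097 without WT1 to -1.32 without WT3). Without WT2 the call was lost over all cells (0.144), in neurons (0.0797), GABAergic neurons (0.838), glutamatergic neurons (0.348), endothelial cells (0.838) and tanycytes (0.788). Without KO3 it was lost over all cells (0.0963), in GABAergic neurons (0.448), glutamatergic neurons (0.314), endothelial cells (0.780) and tanycytes (0.267), in glutamatergic neurons also without WT3 (0.0589) or KO1 (0.125), and in endothelial cells with at least 500 genes per cell (0.272), the adjusted camera p ranging from 1.3e-11 to 0.913 over the alternatives.

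Peptide genes of the list of other hypothalamic peptides were shifted down in glutamatergic neurons, with 6 of 7 members lower (camera adjusted p = 5.8e-04, and adjusted p = 0.913 with an estimated correlation). Adjusted over the list alone 3 members were lower, Tac1 (log2 fold change -1.03 ± 0.26), the enkephalin gene Penk (-1.56 ± 0.40) and the secretogranin gene Scg2 (-0.55 ± 0.18), and none passed over all genes. Penk ran from -1.07 without KO3 to -3.62 without KO1, and passed without KO1 (edgeR adjusted p = 4.8e-07) and WT3 (0.0255), with at least 500 genes per cell, doublets kept and no gene filter, over a range of 4.8e-07 to 0.999. The list was also called down in GABAergic neurons (10 of 15 lower, adjusted p = 0.0158) and over all cells (10 of 15, 0.0176), each with an adjusted p = 0.913 with an estimated correlation. In GABAergic neurons, adjusted over the list alone, 1 member was higher (Gnrh1, 2.73 ± 0.61) and 2 were lower (Tac1, -1.23 ± 0.27, and the neurokinin B gene Tac2, -1.47 ± 0.38). With 1 library left out Gnrh1 ran there from 1.74 without KO3 to 8.29 without WT1, Tac1 from -0.80 without WT3 to -1.50 without WT2 and Tac2 from -1.0 without KO1 to -2.60 without KO2. Over all cells Gnrh1 gave 2.56 ± 0.92 (6.78 without WT1) and Vgf -0.44 ± 0.20. The call over all cells was lost without WT2 (0.0973) and KO3 (0.359) and turned upward without WT1 (0.613), and in GABAergic neurons it was lost without WT1 (0.515) and KO3 (0.326), the adjusted camera p ranging from 1.3e-07 to 0.913 over the alternatives.

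The mitochondrial genome list was called up over all cells (6 of 10 members higher, camera adjusted p = 0.00155), in neurons (7 of 10, 6.5e-04), GABAergic neurons (6 of 10, 0.00473) and astrocytes (10 of 10, 5.8e-04), each with an adjusted p = 0.913 with an estimated correlation. Without mt-Nd3 the adjusted p was 0.518, 0.432, 0.633 and 0.115. Adjusted over the list alone, mt-Nd3 was higher in each of these, and mt-Nd6 in neurons (0.79 ± 0.26). Over all cells mt-Nd6 gave 0.61 ± 0.28 and mt-Rnr1 0.38 ± 0.25. Inflammation genes were called up over all cells with 12 of 13 members higher (camera adjusted p = 0.0119, and adjusted p = 0.913 with an estimated correlation), led by the chemokine genes Ccl12 (0.86 ± 0.32) and Ccl2 (0.92 ± 0.60) and by Cd14 (0.58 ± 0.39, and 0.074 without KO3). The list was not called in microglia (9 of 11 higher, camera adjusted p = 0.135). The values over all cells also take in perivascular macrophages, 0.460% of cells in WT and 0.784% in KO, and unnamed cells with H2-Aa and Cd74, which numbered 2, 8 and 0 in WT and 10, 11 and 21 in KO. Immediate early genes were called down in astrocytes, with 8 of 8 members lower, as were Ier2 (-0.88 ± 0.43), Btg2 (-0.75 ± 0.38) and Egr1 (-0.65 ± 0.36) (camera adjusted p = 0.00354, and adjusted p = 0.913 with an estimated correlation). Ier2 ran from -0.53 without KO1 to -2.34 without KO3 and Egr1 from -0.043 without WT1 to -1.24 without KO3. Interferon response genes were called up in tanycytes, with 7 of 7 higher, B2m at 0.56 ± 0.28, Ifi27 at 0.43 ± 0.25 and Ifit3 at 0.53 ± 0.38, or 1.78 without WT1 (camera adjusted p = 0.00531, and adjusted p = 0.913 with an estimated correlation). No member of the last 3 lists passed, over all genes or adjusted over the list alone. The mitochondrial call was lost over all cells without WT3 (0.130), in GABAergic neurons without WT3 (0.193), KO1 (0.0860) or KO2 (0.0966), and in astrocytes with at least 500 genes per cell (0.060) or without KO2 (0.830), range 9.5e-12 to 0.913. Inflammation was lost with at least 500 genes per cell (0.575), without fibroblast, pituitary, unnamed and 2 KO2-derived neuron clusters (0.0909), and without WT1 (0.118), WT3 (0.210) or KO3 (0.916), range 6.1e-05 to 0.916, immediate early genes with at least 500 genes per cell (0.594) and without WT1 (0.314) or KO1 (0.650), range 2.1e-06 to 0.913, and interferon genes without WT2 (0.199) or KO3 (0.0529), range 3.8e-04 to 0.913 (adjusted camera p).

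LXR targets, genes that respond to cholesterol derivatives, were called down over all cells (6 of 11 lower, camera adjusted p = 0.0341, and adjusted p = 0.913 with an estimated correlation). Mylip is itself a member and was the 1 gene that was lower adjusted over the list alone, while Abca1 gave 0.37 ± 0.18 and Fasn 0.20 ± 0.21. Without Mylip the list pointed up (adjusted p = 0.738), and the call was lost with the replicate block (0.118), without fibroblast, pituitary, unnamed and 2 KO2-derived neuron clusters (0.0563), and without WT3 (0.192), KO1 (0.271) or KO2 (0.330), range 0.00166 to 0.913. The other lists were not called over all cells. IDOL targets and lipoprotein uptake had 8 of 12 members higher (camera adjusted p = 0.534), cholesterol synthesis 13 of 19 lower (0.109), orexigenic peptides and receptors 9 of 11 lower (0.152), and anorexigenic peptides and receptors 9 of 14 lower (0.840), the last with a median log2 fold change of -0.17 and a mean of 0.03 against a test pointing down. GABA and glutamate transmission had 11 of 19 higher (0.940), with a median of 0.05, a mean of -0.01 and a test pointing down, and 1 member, Gabra2, was lower adjusted over the list alone. Synaptic vesicle release had 10 of 18 lower (0.761), insulin and leptin signalling 12 of 18 higher (0.566), glycolysis 12 of 16 lower (0.400), immediate early genes 10 of 16 higher (0.427), heat shock 8 of 13 higher (0.400), interferon response 8 of 11 higher (0.264), genes near Mylip 9 of 15 higher (0.815) and tissue next to the hypothalamus 3 of 5 lower (0.501). Y-linked genes with Xist had under 5 tested members. The Y-linked gene Ddx3y stood at 181 ± 39.1 CPM of all UMIs in WT and 179 ± 25.4 in KO, and Xist had 0, 1 and 2 UMIs in WT and 0, 3 and 0 in KO. Across all classes 21 of 121 tests were called with the preset correlation and 0 with the estimated one.

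Genes on chromosome 13 near Mylip were set out by position because Ly86, Gpr137b and Gpr137b-ps lie on that chromosome, a choice made after their values were seen. Gpr137b (13357620 to 13394014) stood at 18.1 ± 2.51 CPM of all UMIs in WT and 9.93 ± 1.46 in KO, a WT to KO ratio of 1.85 with a 95% counting interval of 1.39 to 2.49. Within 10 Mb of Mylip 103 genes besides Mylip and Ly86 were tested, and 3 (2.91%) had an unadjusted p under 0.05.

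**Figure D4:**
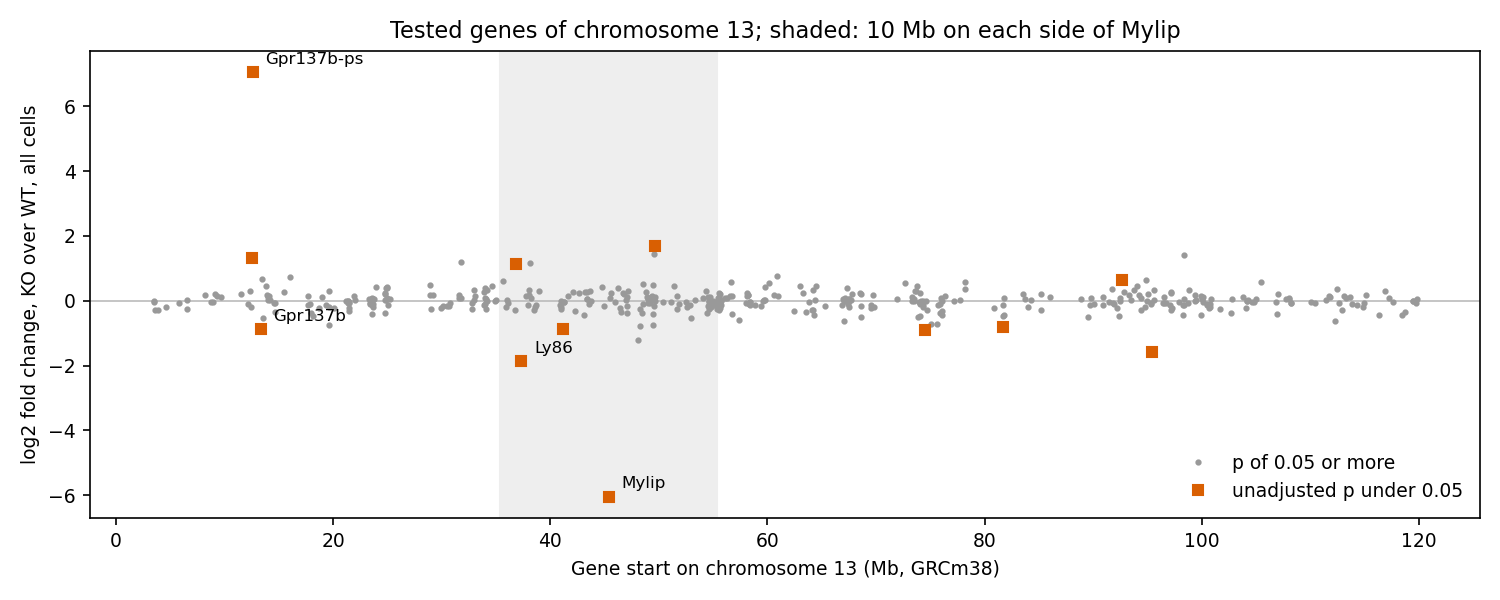
Log2 fold change KO over WT over all cells (vertical axis) against gene start on chromosome 13 in Mb (horizontal axis), with squares for an unadjusted p under 0.05 and shading for 10 Mb on each side of Mylip. Mylip at -6.04 and Gpr137b-ps, at 0 UMIs in WT, stand farthest from 0.

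The difference between KO and WT was unlike in neurons and all other cells for 1 gene, Rbp4, which encodes the plasma carrier of retinol. Its log2 fold change was -0.14 ± 0.43 in neurons and 4.62 ± 1.16 in other cells, a difference of -4.70 ± 0.71 (n = 3 per group, edgeR interaction adjusted p = 0.0204). Fibroblast-like cells carried 115 of the 129 Rbp4 UMIs of KO1 and 162 of the 189 of KO3. KO2 had 8 Rbp4 UMIs in all, against 31, 11 and 12 in WT, so the rise in other cells was present in 2 of 3 KO libraries. Fibroblast-like cells numbered 22, 6 and 72 in KO1, KO2 and KO3 and 5, 11 and 4 in WT1, WT2 and WT3. The rise thus went with the libraries richest in these cells, and a change per cell was not tested. Next came, among others, Crym, a tanycyte marker that binds thyroid hormone (difference 2.21 ± 0.43), Nr4a2 (-2.35 ± 0.50) and Tac1 (-1.65 ± 0.38), with edgeR adjusted p from 0.285 for Crym to 0.854 for Tac1. Crym was also the leading gene of neuron cluster N14, whose 25 cells all came from KO2. Its difference was 1.33 without clusters N14 and N15 and 1.16 without WT1, and it passed without WT3 (edgeR interaction adjusted p = 0.0276) and KO3 (2.0e-04), over a range of 2.0e-04 to 1.00. Of 12410 genes tested 378 (3.05%) had an unadjusted p under 0.05. The Rbp4 call was lost without WT1 (1.00), WT2 (0.0518) or KO1 (0.483) and without the neuron clusters that came from KO2 (0.0833), over an edgeR adjusted p range of 2.6e-05 to 1.00, and 2 genes passed without WT3, 4 without KO2 and 8 without KO3.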

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

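The tests of the chromosome 13 window, the microglial markers and the mix of neuron clusters were set before their results were seen, and the tests of mt-Nd3, of Gpr137b, of Tac1 in non-neuronal cells and of cells rich in Tac1 were chosen only after the result was seen, as were all counts of other splits.

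Rbp4 stood out because the difference between KO and WT was unlike in neurons and other cells, by -4.70 ± 0.71 on the log2 scale (edgeR interaction adjusted p = 0.0204, n = 3 per group). It rested on 2 of 3 KO libraries, those with the most fibroblast-like cells. These numbered 22 in KO1 and 72 in KO3, against 6 in KO2 and 5, 11 and 4 in WT. A change of Rbp4 per cell was not tested. Fibroblast-like cells carried 115 of the 129 Rbp4 UMIs of KO1 and 162 of the 189 of KO3, while KO2 had 8, against 31, 11 and 12 in WT. Without WT1 the adjusted p was 1.00, without WT2 0.0518 and without KO1 0.483. Of the 10 splits of the 6 libraries into 3 and 3, 4 gave at least the 1 gene of the real split, with 7 as the highest other, and 10 splits are too few for a share under 0.05.

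mt-Nd3 had 0 UMIs in the WT libraries and 285, 732 and 104 in the KO libraries. A difference in depth is argued against by a KO to WT ratio of total UMIs of 1.14, and a change in transcription of the whole mitochondrial genome by the median log2 fold change of -0.018 of the other mitochondrial coding genes, which ran from -0.14 ± 0.18 for mt-Cytb to 0.61 ± 0.28 for mt-Nd6. A candidate explanation is a mitochondrial base that sets where reads of mt-Nd3 align, since the reference sequence differs from its nuclear copy Gm28438 on chromosome 1 at 1 of 345 bases (T3C, counted from 1 at the 5' end of the mt-Nd3 transcript) and C57BL/6 substrains are known to differ at a base in mt-Nd3. Coding genes identical to their nuclear copies (mt-Atp6, mt-Co2 and mt-Nd4l) reached at most 1.72 CPM, where more than 10 would have spoken against this explanation, a bound set after the UMIs were seen. The neighbouring transfer RNA gene mt-Tr also rose, with 1, 3 and 1 UMIs in WT and 7, 32 and 21 in KO, so mt-Nd3 did not move alone. Whether a base in mt-Nd3 could move both genes, and which base each group carries, was not tested. The explanation stays open because no reads were available and the base lies at the 5' end while the libraries tag the 3' end. The WT libraries did hold mitochondrial transcripts, with mt-Cytb at 5051, 4420 and 5156 CPM in WT1, WT2 and WT3. The 0 UMIs of mt-Nd3 there thus need not mean that its transcript was absent. An effect of IDOL loss on mt-Nd3 itself was not tested.

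Ly86, Gpr137b and Gpr137b-ps lie on the chromosome of Mylip and differed between the groups. A lower yield or other state of microglia behind Ly86 was set against the 10 fixed microglial markers. Their median log2 fold change inside microglia was -0.083 (lowest P2ry12, -0.42 ± 0.23) while that of Ly86 was -1.92 ± 0.25. Ly86 thus did not fall as part of a general fall of these markers. The same markers named the cells, and levels inside a class do not measure its yield. They therefore cannot exclude a lower yield or another state. Reads of Gpr137b shared with its pseudogene would be consistent with a sum of both genes that changed by -0.13 (SE 0.16, log2) while the share of Gpr137b-ps in it went from 0 in WT to 37.1, 36.0 and 46.8% in KO, as a variant between the groups in either gene may bring about. A segment around Mylip carried over from the founder of the knockout cannot be told apart from an effect of IDOL loss. With these 3 genes and Mylip left out, 2.91% of the 103 genes within 10 Mb of Mylip had an unadjusted p under 0.05 against a median of 1.69% over windows, and 21.4% of 12337 windows had as high a share, neither in the top 5% nor below the median.

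Tac1 was lower in KO neurons. A different mix of neuron clusters is argued against as the whole cause, since cluster shares alone made a change of -0.35 ± 0.09 on the log2 scale where -1.34 was observed. Fewer Tac1 neurons in the dissected tissue cannot be told apart from a lower level per neuron. Tac1 in non-neuronal cells, a measure of free RNA, did not fall with it (log2 fold change 0.24 ± 0.36), but cells with at least 10 Tac1 UMIs numbered 20, 8 and 11 in WT and 13, 5 and 2 in KO, which either would bring about. Inside the cluster with Tac1 and Crhbp the pooled level was 2167 CPM in WT and 1014 in KO, and each KO library was below each WT library. Elsewhere pooled levels went both ways. They fell in clusters N0 (275 to 77.4), N2 (342 to 202), N11 (384 to 57.3) and N13 (580 to 331), and rose in the cluster with Oxt and Avp (223 to 434) and in N6 (11 to 107), and in each of these 6 the WT and KO libraries overlapped. An effect of IDOL loss on Tac1 per neuron stays open, and the DESeq2 adjusted p was 0.822.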

How the results depend on the processing

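The alternatives were planned, except for the robust settings, the fits without cell clusters, the lists without 1 gene and the thinning, which were chosen after the data had been seen. For the reported single genes, list calls and shares, 1614 planned values kept their direction and side of the threshold or moved by less than the spread between libraries. Beside these, a call was lost in 107 planned values and gained in 52, the direction turned in 4 and 1 moved further. A gene that passed neither in the main fit nor in the alternative counts as kept. The 1614 therefore do not measure how stable the calls were. Among called genes, Nts in GABAergic neurons lost its call in 9 of 15 alternatives and Mylip in microglia in 6 of 13. Among added values 214 stayed, 13 lost a call, 1 gained one and 1 turned. For counts of genes and other main results 100 planned values stayed within 1.5 times or on their side of the threshold, 63 moved and 2 gained the call. Among added ones 10 stayed, 7 moved and 1 gained it. Ly86 in microglia passed in its 13 alternatives (edgeR or DESeq2 adjusted p at most 0.0146), Scrg1 in oligodendrocytes in its 14 (at most 0.00119) and Gm8773 in GABAergic neurons in the 14 that tested it (at most 0.0224). With at least 500 genes per cell Gm8773 did not reach the gene filter there. No alternative can separate IDOL loss from another difference between the groups, such as genetic background. Passing in each of them therefore does not tie Ly86, Scrg1 or Gm8773 to IDOL. Median UMIs per cell differed by -57.8 between groups, and by -98.5 with at least 500 genes per cell.

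For the values below, the cause was not tested unless it is given. Mylip over all cells gained its call with DESeq2 (log2 fold change -6.29), with no gene filter (-6.04) and without fibroblast, pituitary, unnamed and clusters N14 and N15 cells (-6.59), and ran from -8.64 to -5.50 with 1 library left out.

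With the DESeq2 Wald test 4 genes passed over all cells, 2 in neurons and 0 in astrocytes. With no gene filter 1 passed over all cells, 23 in neurons, 23 in GABAergic neurons, 10 in glutamatergic neurons, 7 in astrocytes, 12 in oligodendrocytes, 2 in OPC, 11 in microglia, 9 in endothelial cells and 7 in tanycytes. With at least 500 genes per cell 1 passed in GABAergic neurons, 2 in glutamatergic neurons, 0 in astrocytes and 1 in oligodendrocytes, from fewer cells, and 1 class share did not overlap. With doublets kept 2 passed in glutamatergic neurons and 6 in oligodendrocytes. With Leiden resolution 0.5 none (0) passed in glutamatergic neurons, where edgeR and DESeq2 each called 1 otherwise. With robust settings 2 passed in neurons, 1 in GABAergic neurons, 1 in astrocytes, 1 in oligodendrocytes and 1 in microglia. Without fibroblast, pituitary, unnamed, N14 and N15 cells 1 passed over all cells. The interaction had 0 without N14 and N15. Camera with an estimated correlation called 0 lists.

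With the replicate block, which takes the replicate number as a covariate, 1 gene passed over all cells, 7 in neurons, 0 in glutamatergic neurons, 11 in oligodendrocytes and 5 in microglia, among them Apoe, Ly86, Mbp and Mylip. The numbers did not pair the libraries throughout, and over all cells the deviations of same-numbered libraries correlated across genes at 0.26, -0.15 and 0.24. In each single class tested WT1 was nearest to KO2, WT2 to KO1 and WT3 to KO3. In neurons these correlations were 0.11, 0.18 and 0.17. Whether the pattern follows the days of preparation was not tested, and no test took it into account.

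With 1 library left out, the count of passing genes ran from 0 to 1 over all cells (1 without KO2 or KO3), 2 to 8 in neurons (8 without KO1, 2 without KO2, 8 without KO3) and 2 to 11 in GABAergic neurons (5 without WT1, 11 without KO1, 5 without KO2). In glutamatergic neurons it ran from 0 to 5 (4 without WT1, 5 without WT3, 4 without KO1, 0 without KO2, 2 without KO3), in astrocytes from 0 to 3 (1 without WT3, 0 without KO2) and in oligodendrocytes from 2 to 5 (5 without KO1). OPC ran from 0 to 2 (2 without WT2, 1 without WT3, KO1, KO2 or KO3), microglia from 1 to 7 (7 without WT1, 1 without WT2, 5 without KO1, 1 without KO2), endothelial cells from 0 to 2 (2 without WT3, 1 without KO3) and tanycytes from 0 to 2 (2 without KO3). The interaction ran from 0 to 8 (0 without WT1, WT2 or KO1, 2 without WT3, 4 without KO2, 8 without KO3), called lists from 19 to 30, and class shares that did not overlap from 2 to 5 of 17 (4 without WT3, 5 without KO2), where chance gives 20%.

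Direction turned for LXR targets without Mylip (camera adjusted p = 0.738), which was the member with by far the lowest value, and for other hypothalamic peptides over all cells without WT1 (0.613, range with 1 library left out 1.8e-05 to 0.613). It also turned for Apoe over all cells without KO1 (0.054, range -0.26 to 0.054), Fasn over all cells without KO3 (-0.014, range -0.014 to 0.35) and mt-Rnr1 in GABAergic neurons without KO1 (-0.044, range -0.044 to 0.63), none of which had passed. Microglia and tanycytes were not run at 500 genes per cell, and mural and ependymal cells not at all, because a library held under 20 cells. Mylip had 2 UMIs in all in oligodendrocytes, 2 in OPC and 3 each in mural and ependymal cells, so at this depth its loss was not detectable there.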

Other observations

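The counts of other splits were chosen only after the results were seen, and the remaining values in this part were picked after they were seen and carry no test.

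Microglia fell into 2 clusters. One was led by the cytokine and chemokine genes Il1a, Ccl4 and Tnf, with 35, 26 and 38 cells in WT and 28, 47 and 52 in KO, and the other by the resting-state genes P2ry12 and Tmem119, with 28, 17 and 35 cells in WT and 23, 28 and 32 in KO. A cluster of 13 OPC carried the cell division genes Top2a and Mki67. Among unnamed cells, 52 carried the antigen presentation genes H2-Aa, H2-Ab1 and Cd74, with 2, 8 and 0 in WT and 10, 11 and 21 in KO. Another 190 carried the pericyte genes Rgs5, Kcnj8 and Vtn beside Car4, with 17, 14 and 27 in WT and 21, 38 and 73 in KO. A group of 68 with Slc26a7, Slc47a1 and Rspo3 had 0, 14 and 2 cells in WT and 12, 13 and 27 in KO.

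Several hypothalamic peptides came from a few cells. Pmch, melanin-concentrating hormone, had 155, 8 and 593 UMIs in WT and 13, 368 and 68 in KO, with 567 of those of WT3 in 1 cell and 349 of those of KO2 in 1 cell. Gnrh1 had 162, 2 and 1 UMIs in WT and 168, 202 and 477 in KO, with 168 of those of KO1, 199 of those of KO2 and 442 of those of KO3 in 1 cell each. Nts had 163, 19 and 55 UMIs in WT and 164, 155 and 324 in KO, with 168 of those of KO3 in 1 cell. Hcrt, orexin, had 52, 43 and 12 UMIs in WT and 5, 8 and 19 in KO, and Oxt, oxytocin, 6861, 1318 and 772 in WT and 621, 101 and 3799 in KO.

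Some cells and transcripts came from single libraries. Neuron cluster N14 with Neurod2 and Slc17a7 held 25 cells, all from KO2, and N15 with Reln and Trp73 held 21, of which 19 were from KO2. Cga, a pituitary hormone gene, had 446 UMIs in KO1, 1 in KO3 and 0 in the others. Of 78 fibroblast-like cells in one cluster with Rbp4 among its leading genes, 55 were from KO3. The mitochondrial arginine transfer RNA gene mt-Tr (9808 to 9875 on the mitochondrial chromosome), next to mt-Nd3, had 1, 3 and 1 UMIs in WT and 7, 32 and 21 in KO, a ratio of 10.6 (95% counting interval 4.29 to 33.7). Nnt, a gene known to differ between C57BL/6 substrains, stood at 13.2 ± 2.23 CPM of all UMIs in WT and 17.1 ± 2.04 in KO, and its groups overlapped. Gabra2 stood at 108 ± 26.9 CPM of all UMIs in WT and 58.1 ± 4.89 in KO, without overlap. Whether a difference in genetic background lies behind either gene was not tested.

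Each count of passing genes was also taken for the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05. In neurons 1 split gave the real count of 4 (highest other 3), in GABAergic neurons 3 gave at least the real 3 (highest other 3), in glutamatergic neurons 8 the real 1 (highest other 4), in astrocytes 4 the real 2 (highest other 4), in oligodendrocytes 1 the real 2 (highest other 1) and in microglia 1 the real 2 (highest other 0). Over all cells and in OPC, endothelial cells and tanycytes the real count was 0 (edgeR, with 262, 145, 101 and 98 genes at an unadjusted p under 0.05 and 4, 0, 0 and 0 by DESeq2). Each of the 10 splits reaches 0, so their number says nothing there, and the highest others were 0, 5, 4 and 3. For called lists 8 splits gave at least the real 21, and the highest other gave 48.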
